A study of Homo sapiens with 9 samples.

How the data were processed

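RNA abundance was measured by RNA sequencing in cultured human coronary artery smooth muscle cells, the contractile cells of the coronary artery wall. The series holds 9 libraries: 3 from cells given a dicer-substrate RNA against SENCR, 3 from cells given a control sequence, and 3 from untreated cells grown under normal conditions. Per the labels' protocols, both RNAs were used at 30 nM and cells were harvested after 3 days. RNA was purified with an RNeasy kit, cDNA was made with dT-T7 primers, and the libraries were read on an Illumina Genome Analyzer IIx. Such primers select poly(A) tails. Rows of RNAs that typically lack one, such as replication-dependent histone and mature small RNAs, need not measure those RNAs. The labels do not say whether the replicates came from separate cultures or donors, so p-values measure only the spread between these samples, which may be technical.

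The authors deposited FPKM, which scales fragments to transcript length and to the library's mapped fragments, per the file headers. One table holds FPKM for each of the 6 libraries of the knockdown experiment over 25548 rows, and the other holds only the authors' mean FPKM of the 3 untreated libraries over 59159 rows. Per the submitters' processing notes, the builds were GRCh37 and hg19 and the tools CASAVA 1.8.2 and Cufflinks 2.0.2, with no role stated for either tool. The aligner, the annotation, any filter and any use of strand are not given in the sources used here. FPKM divides by transcript length and by the library's total, so a few abundant transcripts can shift all other values, and reads of overlapping genes or near-identical paralogs are divided by a rule that is not stated. Starts in the untreated table were 1 below the annotation for 8 of 8 mitochondrial genes compared. The knockdown table has no mitochondrial rows; the lengths of 509 of 511 of its microRNA rows equal those of the annotation if starts count from 0, and 1 if they count from 1. Starts in both were therefore read as counted from 0 and are given here counted from 1.

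Columns were matched to samples by name. The 3 columns called ctrl carry the numbers of the control titles. The other 3 columns are called L9, which the labels do not explain. They were taken as the knockdown libraries because only the knockdown and control samples name this table, and RefSeq lists lncRNA9 as a synonym of SENCR. SENCR has no row under that name: the row LOC100507392 was identified as SENCR through its RefSeq gene ID, which also has the synonym FLI1-AS1. Of 3083 rows named LOC and a number, 1778 had a RefSeq gene ID. The reference in use was GENCODE 29 for transcript length, GC content and long non-coding RNA names, and RefSeq for names only. Length and GC content were those of the longest transcript of each name. Both references are on a later build, so no coordinate was taken from them.

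The comparison of knockdown with control used limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with an empirical Bayes trend, no covariate and no block, for rows with a mean of at least 1 FPKM over the 6 libraries. P-values are two-sided and adjusted by Benjamini-Hochberg over the rows tested, with a threshold of 0.05. Log2 fold changes are knockdown minus control on the log2(FPKM + 1) scale, which understates the change of low genes; plain ratios of mean FPKM are given as folds. For SENCR and FLI1 an exact two-sided permutation test was added, whose smallest p with 3 against 3 libraries is 0.1. Gene lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over 21 lists, and again with an estimated correlation and with fry. Of the 21 lists, 14 passed camera, 0 passed with an estimated correlation, 14 passed fry's directional test and 18 its mixed test; fry does not compare a list with other genes. Values in the untreated cells come from a table normalized separately and were not tested against the other.

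The 25 lists covered smooth muscle contraction, MRTF and SRF response, migration and promigratory factors, extracellular matrix, proliferation, interferon response, inflammatory cytokines and NF-kB, cholesterol synthesis, endoplasmic reticulum stress, p53 targets, hypoxia and glycolysis, TGF-beta targets, heat shock, cytosolic ribosomal proteins, the nuclear-encoded respiratory chain, replication-dependent histones, ETS-family and endothelial transcription factors, long non-coding RNAs, the SENCR locus, and markers of endothelial cells, fibroblasts, leukocytes, cardiac and skeletal muscle, epithelium, and fat, bone and cartilage. The test, the lists and the rule for named genes were fixed before the data were examined. The rule names the members of the SENCR locus, 9 genes the published study examined, the 10 called genes with the largest change in each direction whose groups do not overlap, up to 4 members of each list by smallest p, and in untreated cells the 10 highest named rows, the 5 highest listed long non-coding RNAs and up to 4 members of each marker list. Genes outside the rule are said to be chosen after their values were seen.

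Absolute depth is unknown, because FPKM holds no read totals. Relative depths were read from the most common ratio to control 1 over rows of microRNAs, small nucleolar and other small RNAs, shared by 30 to 48 rows per library. With control 1 set to 1, they were 0.929 and 0.835 for controls 2 and 3 and 1.019, 0.822 and 0.822 for knockdowns 1, 2 and 3. With these depths, 350 of 377 tested small RNA rows (92.8%) came out as whole reads in all 6 libraries, within a tolerance of 2%. Rows with reads in only 1 library, or with many reads, pass this check by construction, so it does not test the depths. Read numbers quoted for small RNA rows are the smallest whole numbers in the ratio of the values. An exact 0 can be a failed estimate, since FN1, a highly expressed gene, is listed at 0 in 1 library and at 1806 FPKM or more in the other 5. Genes with a group at 0 therefore get values per library and no fold. Rows for which reads of neighbours cannot be told apart (3189 of 11364 tested share an interval with another row) were kept and left out in an alternative.

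On simulated data with the spread of these libraries, in 5 runs over 11364 genes with 200 changed genes each, the knockdown comparison recovered 84% of genes changed by 0.5 and 96.2% of those changed by 1 on the log2 scale, and called on average 7.2 unchanged genes per run. The simulated noise was independent between genes, so this number does not cover false calls from shifts that many genes share. Alternatives set beforehand were pseudocounts of 0.1, 0.5 and 5, no filter and filters at 0.1 and 5 FPKM, quantile, median-of-ratios and upper-quartile scaling, empirical Bayes without a trend or robust, library weights, the replicate number as a block, leaving out each library, an adjusted p of 0.01, and the other list tests. Added after seeing the data were cyclic loess, removal of GC and length trends per library, and leaving out small RNAs, rows with a 0 or rows sharing a locus. Random lists matched on expression were drawn 10000 times. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with pandas 2.3.3 and numpy 2.4.6.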

Results

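SENCR is a long non-coding RNA of vascular cells that lies antisense to FLI1, the gene of an ETS-family transcription factor. The series asked which transcripts change in human coronary artery smooth muscle cells when SENCR is lowered, after a first set of untreated libraries had been sequenced to find long non-coding RNAs. Knockdown and control RNA had 3 libraries each. Their FPKM summed to 223965, 231859 and 233647 in the knockdowns and to 251908, 250354 and 239464 in the controls, and between 11078 and 11312 rows per library reached 1 FPKM. Log2 values correlated across genes between libraries of the same group at 0.9772 to 0.9851 (6 pairs) and between groups at 0.9779 to 0.9814 (9 pairs). Group values below are mean FPKM ± SD over 3 libraries, and adjusted p-values are from limma. In the comparison, DES, FOSL1, GAPDH, FN1, TGFB1, MYH6, CDH5 and MIR143HG were singled out only after their values were seen.

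SENCR itself (row LOC100507392, 11:128561567-128683162, GRCh37) was lower in every knockdown library than in every control library. It stood at 0.809, 0.584 and 0.841 FPKM in the knockdowns against 1.19, 1.09 and 1.13 in the controls, so that 65.5% of the control mean was left (0.745 ± 0.14 against 1.14 ± 0.0484). The exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 libraries allow. The row misses the filter of 1 FPKM; with the filter at 0.1 FPKM its log2 fold change was -0.30 (SE 0.0648, adjusted p = 0.0369). SENCR and FLI1 are listed with the same interval, and no use of strand is stated, so reads of the pair cannot be told apart.

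FLI1, which shares that interval, was 1.16-fold higher in knockdown (4.27 ± 0.177 against 3.68 ± 0.097, log2 fold change 0.17, SE 0.0358, adjusted p = 0.0272), with the exact permutation p again 0.1. Its call was lost when any 1 of the 6 libraries was left out (log2 fold change 0.14 to 0.19, adjusted p from 0.0553 to 0.0873), without a filter (0.0539), with the replicate block (0.0596) and with the block and GC and length trends removed (0.0561). Its adjusted p ranged from 0.0185 to 0.0873 over 23 alternatives. ETS1, a related transcription factor upstream on the same chromosome (11:128328656-128457453), fell from 15.3 ± 0.221 to 13.2 ± 0.29 (log2 fold change -0.19, adjusted p = 0.0128), a call lost with the replicate block (adjusted p = 0.0605). ARHGAP32 was at 1.71 and 1.53 FPKM (adjusted p = 0.257) and KIRREL3 at 1.55 and 1.64 (adjusted p = 0.634). KCNJ1, KCNJ5, C11orf45 and TP53AIP1 stood at 0.278 FPKM or less in every library and were not tested.

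**Figure D1:**
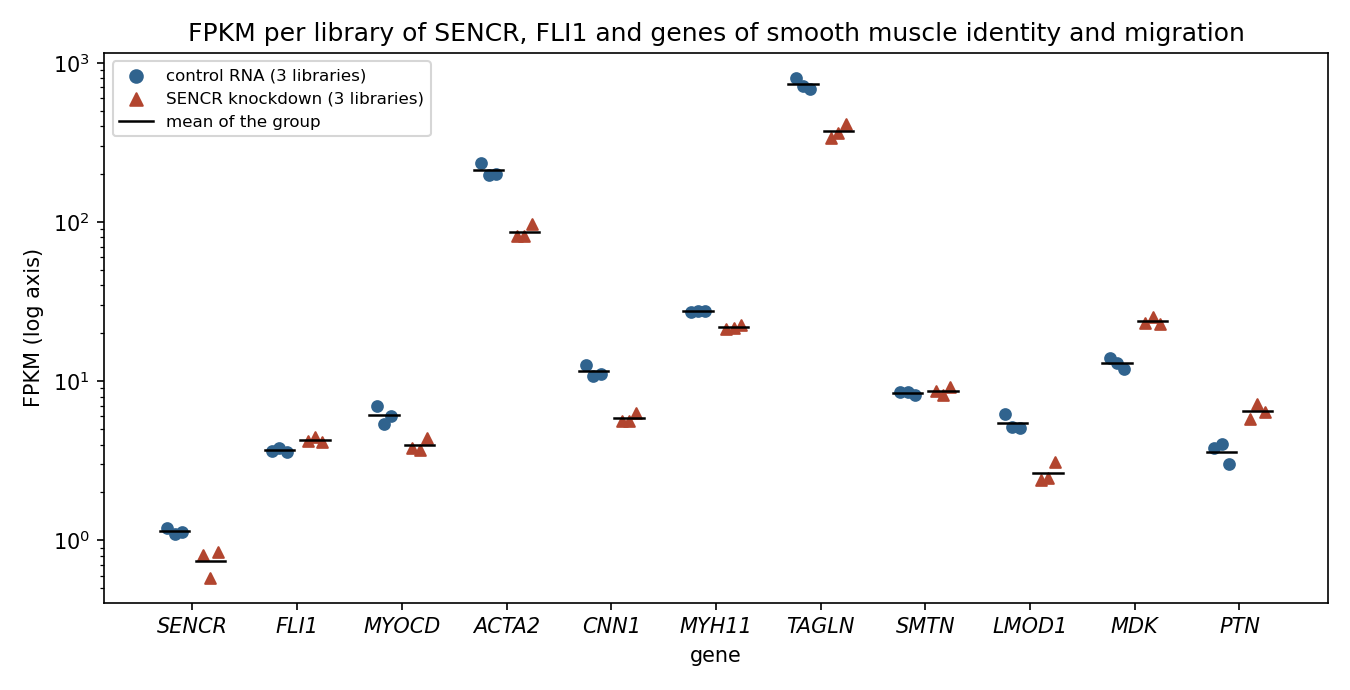
FPKM on a log axis for SENCR, FLI1 and 9 genes the study examined; each point is 1 library and each black line the mean of 3 libraries of a group. The 3 knockdown libraries lie below all controls for SENCR, MYOCD, ACTA2, CNN1, MYH11, TAGLN and LMOD1, above them for FLI1, MDK and PTN, and among them for SMTN.

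Most tested genes of the contractile apparatus were lower (28 of 35). ACTA2 (10:90694831-90775542), the smooth muscle alpha-actin, went from 211.8 ± 20.7 to 86.9 ± 9.12 FPKM, 2.44-fold lower (log2 fold change -1.28, SE 0.0985, adjusted p = 0.00216). TAGLN (11:117070040-117075508), the actin-binding protein SM22, fell from 733 ± 62.5 to 371 ± 36.5 (log2 fold change -0.98, adjusted p = 0.00292). CNN1 (19:11649579-11661138), the calponin of smooth muscle, fell 1.96-fold to 5.87 ± 0.376 (adjusted p = 0.00229), and LMOD1 (1:201865584-201915716), the smooth muscle leiomodin that nucleates actin filaments, 2.06-fold to 2.67 ± 0.396 (adjusted p = 0.00587). MYH11 (16:15737124-15950887), the smooth muscle myosin heavy chain, fell less, from 27.6 ± 0.271 to 21.8 ± 0.683 (log2 fold change -0.32, adjusted p = 0.00384).

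MYOCD (17:12569207-12670651), the transcriptional coactivator of the contractile genes, fell from 6.13 ± 0.825 to 3.97 ± 0.399 (log2 fold change -0.52, SE 0.0979, adjusted p = 0.0204). This call was lost without knockdown 1 (adjusted p = 0.0711), knockdown 2 (0.0654) or control 3 (0.0593), with the replicate block (0.0544) and with the block and GC and length trends removed (0.0641). The adjusted p ranged from 0.00475 to 0.0711 over 25 alternatives. SMTN (22:31477282-31500610), which encodes smoothelin, was at 8.65 ± 0.519 in knockdown and 8.43 ± 0.191 in control (log2 fold change 0.03, adjusted p = 0.664), with a sign that turned without knockdown 3 (-0.007). In the opposite direction, the heparin-binding growth factors midkine and pleiotrophin rose: MDK (11:46402618-46405375) 1.83-fold to 23.8 ± 1.23 (adjusted p = 0.00223) and PTN (7:136912088-137028546) 1.79-fold to 6.45 ± 0.705 (adjusted p = 0.0109). ACTA2, MYH11, SMTN and PTN share their interval with another row, as do HECW2, ALDH1A3, HIST1H2AD and SAA2 below, so their share of reads is uncertain. In untreated cells, normalized separately, MYH11 and PTN were at only 1.69 and 0.35 FPKM.

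Across the transcriptome, 1963 of 11364 tested rows changed, 865 higher and 1098 lower (44.1% higher), and 3754 had an unadjusted p under 0.05. The changes were small: the median size among changed rows was 0.254 on the log2 scale, and 4 rows rose and 18 fell by 1 or more. All 4 that rose and 2 that fell by that much are small RNA rows listed at 0 in a whole group, and the largest other rise was 0.906. The groups did not overlap in 4442 rows (39.1%, where chance gives 10%). Leaving out a library gave from 961 changed rows (without control 1) to 1127 (without knockdown 3), with 964 without knockdown 1, 1001 without knockdown 2, 1008 without control 2 and 1121 without control 3. Median log2 fold changes went from 0.047 in the lowest of 10 expression classes of equal size to -0.114 in the highest.

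Among the genes with the largest rise were HECW2 (2:197063977-197457335), a ubiquitin ligase (2.20-fold, adjusted p = 0.00313), and ALDH1A3 (15:101420009-101610317), a retinaldehyde dehydrogenase (1.82-fold, adjusted p = 0.00448). THBD (20:23026270-23030301), the thrombin receptor thrombomodulin, rose 2.79-fold from 0.696 to 1.94 FPKM (adjusted p = 0.00183), and AKR1C4 (10:5238798-5260910), an aldo-keto reductase, 1.76-fold (adjusted p = 0.00292). AKR1C4 has close paralogs, and the sharing of their reads is uncertain. The histone gene HIST1H2AD (6:26197012-26199471) was 2.01-fold higher (log2 fold change 0.88, adjusted p = 0.0329). This call was kept in 16 of 24 alternatives (adjusted p from 0.00766 to 0.0954) and lost without knockdown 1, 2 or 3 or control 1, without a filter (0.0553), with robust empirical Bayes (0.0587), with the replicate block (0.0876) and with the block and GC and length trends removed (0.0918).

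The largest falls included NPPB (1:11917521-11918992), which encodes the natriuretic peptide BNP, from 6.89 ± 1.3 to 1.68 ± 0.433 FPKM (4.10-fold, log2 fold change -1.56, adjusted p = 0.00331). The acute-phase serum amyloid genes SAA1 (11:18287808-18291524) and SAA2 (11:18252902-18270221) and the related pseudogene SAA3P (11:18134019-18137679) fell 2.75-, 2.70- and 2.78-fold (adjusted p = 0.00525, 0.0092 and 0.00458). SAA1 and SAA2 are near-identical copies and may share reads. TNFRSF11B (8:119935796-119964383), the decoy receptor osteoprotegerin, fell from 128.5 ± 2.79 to 55.5 ± 1.87 (adjusted p = 0.000416). ACTBL2 (5:56775843-56778636), a beta-actin-like gene, fell 2.53-fold (adjusted p = 0.00289), and LOC100131774, which shares its interval with CTGF (6:132266630-132272518), 2.29-fold (adjusted p = 0.000553).

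The rule for named genes also took 6 small RNA rows, each listed at 0 in a whole group. MIR4482 (10:106028094-106028163) was listed at 45.7, 28.3 and 56.6 FPKM in knockdown (2, 1 and 2 reads) and at 0 in control. SNORD14B (11:17095939-17099220) was at 38.4, 11.9 and 11.9 and SNORA9 (7:45022627-45026259) at 10.8, 3.34 and 3.34, both 4, 1 and 1 reads, with 0 in control. SNORA56 (X:153991031-154005964) was at 2.98, 3.70 and 3.71 (1, 1 and 1 reads) against 0. In the other direction SNORD4A (17:27047000-27053949) was listed at 21.2, 22.8 and 25.4 in control (1, 1 and 1 reads) and MIR4680 (10:112631553-112679124) at 58.1, 21.1 and 9.36 (15, 5 and 2 reads), with 0 in knockdown. Read numbers given here are the smallest whole numbers in the ratio of the values and so lower limits. Of 377 tested small RNA rows 7 were called in all. With dT-primed cDNA, these rows need not measure the mature small RNAs.

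The contractile list as a whole was lower: 28 of its 35 tested members fell and 0 rose, or 30 and 1 when adjusted over the list alone. Part of the list was chosen by the study on these samples, so neither count is independent evidence of its direction. Examples beyond the genes above were SYNPO2, which binds actin (1.83 ± 0.0424 against 3.71 ± 0.164 FPKM, adjusted p = 0.000836), the caldesmon gene CALD1 (log2 fold change -0.55, adjusted p = 0.00155), the tropomyosin gene TPM1 (log2 fold change -0.60, adjusted p = 0.00168) and NEXN (log2 fold change -0.54, adjusted p = 0.0013). The median log2 fold change was -0.52 (camera adjusted p = 5.09e-19; adjusted p = 0.25 with an estimated correlation), and -0.31 after quantile normalization. DES, the desmin gene, was at 41.1 and 43.5 FPKM (adjusted p = 0.217).

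In the MRTF and SRF growth-response list, 10 of 17 tested members fell and 1 rose, with the same counts when adjusted over the list alone and 5 to 7 lower with 1 library left out. The matricellular genes CTGF (1.89-fold, adjusted p = 0.000499) and CYR61 (1.53-fold, adjusted p = 0.00208) and the cytoplasmic actins ACTG1 (log2 fold change -0.49) and ACTB (-0.48) fell; FOSL1, a subunit of AP-1, rose. The list's median was -0.22 (camera adjusted p = 0.000266; adjusted p = 0.328 with an estimated correlation). After cyclic loess the median was -0.126 and ACTB and ACTG1 were still called, at -0.213 and -0.235. GAPDH, a common reference gene, fell in the same way, from 1232 to 885 FPKM (log2 fold change -0.48, adjusted p = 0.0074), and by less after cyclic loess (-0.201), a call lost with the replicate block (adjusted p = 0.0557).

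Migration and promigratory genes went both ways: of 31 tested, 12 rose and 6 fell (14 and 6 when adjusted over the list alone). MDK, PTN and possibly other members were chosen by the study on these samples, so the direction is not independent evidence. Besides MDK, the semaphorin and VEGF coreceptor NRP1 rose from 61.7 ± 0.393 to 83.5 ± 1.25 (adjusted p = 0.00173), while the growth factor FGF2 fell from 112.5 ± 1.34 to 83.2 ± 0.878 (adjusted p = 0.00173) and the matricellular THBS1 from 992 ± 22.4 to 716 ± 21.2 (adjusted p = 0.00216). The median was 0.18 (camera adjusted p = 0.0391; adjusted p = 0.359 with an estimated correlation). The list's call was lost without knockdown 1 (0.112), knockdown 3 (0.0559) or control 2 (0.102), with the replicate block (0.0512) and without rows sharing a locus (0.0684). The adjusted p ranged from 0.000975 to 0.112 over 25 alternatives.

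Extracellular matrix genes were mostly lower where they changed, with 16 of 41 tested fallen and 1 risen (17 and 4 when adjusted over the list alone, 9 lower and 0 higher with the replicate block). HAPLN1, which links hyaluronan and proteoglycans, fell 2.33-fold to 1.85 ± 0.0991 (adjusted p = 0.00156), the crosslinking enzyme LOX from 131.6 ± 0.588 to 92.9 ± 2.57 (adjusted p = 0.00173), periostin (POSTN) from 442 ± 13.1 to 301 ± 14.1 (adjusted p = 0.00246) and the basement membrane collagen COL4A1 1.57-fold (adjusted p = 0.00278). The median of -0.074 turned to 0.006 after cyclic loess. Camera gave an adjusted p of 0.000296 (adjusted p = 0.404 with an estimated correlation), but 0.329 after quantile normalization (7 higher, 10 lower) and 0.472 after cyclic loess (6 higher, 11 lower), in a range of 8.78e-06 to 0.472 over 25 alternatives. FN1, the fibronectin gene, was listed at 0 in control 1, at 2478 and 2589 FPKM in the other controls and at 1809, 1806 and 1964 in the knockdowns.

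TGF-beta targets also moved in both directions, 4 of 24 tested higher and 7 lower, with the same counts when adjusted over the list alone and 1 and 4 with the replicate block. The receptor TGFBR1 fell 1.66-fold to 4.28 ± 0.225 (adjusted p = 0.00155), the elastin gene ELN from 10.2 to 6.82 FPKM (adjusted p = 0.00281) and INHBA 1.51-fold (adjusted p = 0.00693). The ligand TGFB1 rose from 10.5 to 13.8 FPKM (adjusted p = 0.00723). Camera gave an adjusted p of 0.0408 (adjusted p = 0.359 with an estimated correlation), which rose to 0.109 after quantile normalization, 0.0564 with median-of-ratios factors, 0.0509 with upper-quartile scaling and 0.209 after cyclic loess. The call was also lost without knockdown 2 (0.0615), control 1 (0.0562) or control 3 (0.076), with a filter of 5 FPKM (0.449) and without rows sharing a locus (0.0684), and the range over 25 alternatives was 0.0139 to 0.449.

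**Figure D2:**
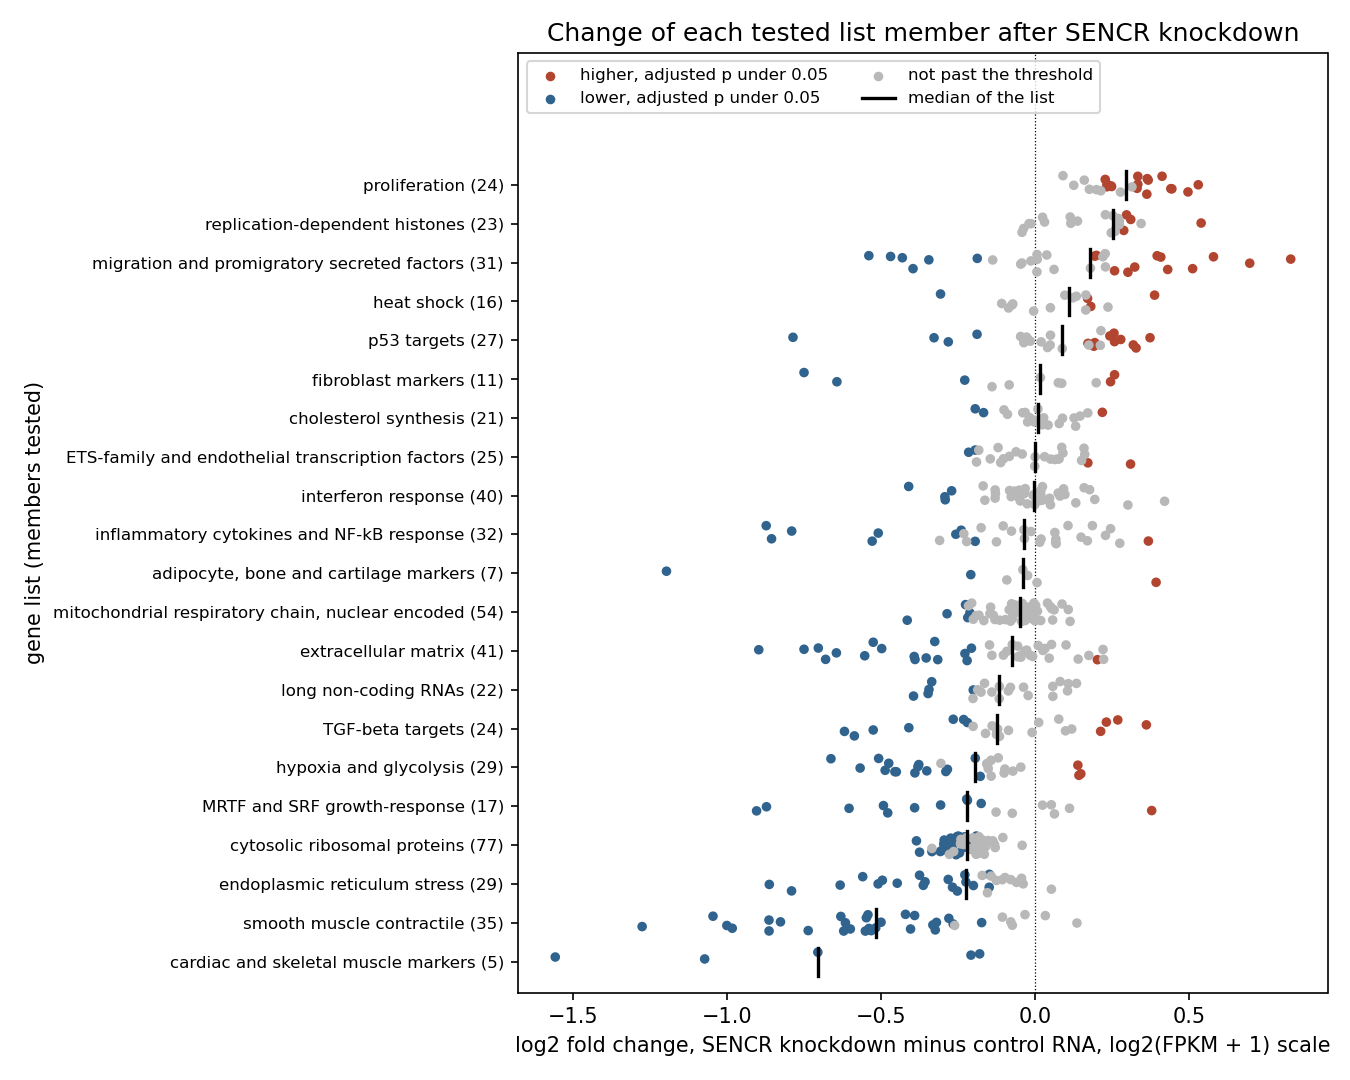
Log2 fold change, knockdown minus control, of each tested member of 21 lists; each point is 1 gene, coloured where its adjusted p is under 0.05, and each black line is the median of its list. FN1, listed at 0 in 1 library, is not drawn; the contractile list has a median of -0.52 and the proliferation list of 0.295.

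Of 24 tested proliferation genes 16 were higher and 0 lower (22 and 0 when adjusted over the list alone, but 6 to 9 higher with 1 library left out and 6 with the replicate block). Levels were low: the ribonucleotide reductase subunit RRM2 went from 1.8 ± 0.0916 to 3.04 ± 0.146 FPKM (adjusted p = 0.00229), the replicative helicase subunits MCM4 and MCM3 rose by 0.41 and 0.50 on the log2 scale (adjusted p = 0.00246 and 0.00736), and the spindle protein gene TPX2 1.46-fold (adjusted p = 0.00843). The median was 0.295 (camera adjusted p = 3.61e-10; adjusted p = 0.25 with an estimated correlation). Replication-dependent histone genes had 5 of 23 tested higher and 0 lower (8 and 0 when adjusted over the list alone, but 0 higher without control 2 or control 3, 1 without control 1 and 2 with the replicate block) and a median of 0.252 (camera adjusted p = 0.00153; adjusted p = 0.328 with an estimated correlation). HIST1H2BG rose from 2.81 to 4.57 FPKM (limma adjusted p = 0.0239), a call lost without knockdown 3 or any 1 of the controls (adjusted p up to 0.0778). With dT-primed cDNA, the histone rows need not measure the main histone mRNAs, which typically lack a poly(A) tail.

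Of 27 tested p53 targets 10 rose and 4 fell (11 and 4 when adjusted over the list alone, but 5 to 7 and 1 to 3 with 1 library left out and 3 and 1 with the replicate block). FDXR rose 1.38-fold and the DNA repair gene XPC 1.38-fold (adjusted p = 0.00321 and 0.00723), SPATA18 rose 1.44-fold (adjusted p = 0.00716), and CCNG1 fell 1.23-fold (adjusted p = 0.00384). The median was 0.088 (camera adjusted p = 0.0219; adjusted p = 0.328 with an estimated correlation). The list's call was lost with a filter of 5 FPKM (0.423) and without rows sharing a locus (0.0508), in a range of 0.0128 to 0.423 over 25 alternatives.

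Endoplasmic reticulum stress genes were lower where they changed, 18 of 29 tested lower and 0 higher (22 and 0 when adjusted over the list alone, and 8 lower with the replicate block). CHAC1, a target of ATF4 that degrades glutathione, fell 2.29-fold to 1.72 ± 0.13 (adjusted p = 0.000865), ASNS, asparagine synthetase, 1.82-fold (adjusted p = 0.00216), HERPUD1 from 30.2 to 20.2 FPKM (adjusted p = 0.00173) and the chaperone gene DNAJB9 1.31-fold (adjusted p = 0.00229). The median was -0.225 (camera adjusted p = 8.96e-12; adjusted p = 0.25 with an estimated correlation), and -0.143 after cyclic loess.

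Hypoxia and glycolysis genes were lower in 15 of 29 tested cases and higher in 3 (22 and 3 when adjusted over the list alone, but 10 to 13 and 0 to 1 with 1 library left out and 8 and 0 with the replicate block). The vasodilator peptide gene ADM fell from 45.7 to 28.5 FPKM, the mitochondrial protein gene BNIP3 1.49-fold, PDK1 1.30-fold, and LDHA from 457 to 334 FPKM (adjusted p = 0.00331, 0.00246, 0.00331 and 0.00292). The median was -0.195 (camera adjusted p = 4.82e-09; adjusted p = 0.359 with an estimated correlation).

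Cytosolic ribosomal protein genes were lower in 38 of 77 tested and higher in 0 (66 and 0 when adjusted over the list alone). That count hung on single libraries: 2 were lower without control 1, 3 without knockdown 1 or control 2, 9 without knockdown 2 or 3, 39 without control 3 and 0 with the replicate block. The falls were small: RPL10 went from 97.2 ± 4.38 to 74.7 ± 4.11 FPKM (adjusted p = 0.0106) and RPSA from 185 ± 7.22 to 141.5 ± 9.11 (adjusted p = 0.011). The median of -0.223 (camera adjusted p = 5.09e-19; adjusted p = 0.359 with an estimated correlation) shrank to -0.034 after quantile normalization and -0.04 after cyclic loess, each with 10 members lower. With median-of-ratios factors and upper-quartile scaling 62 and 63 members were lower. Nuclear-encoded respiratory chain genes had 5 of 54 tested lower and 0 higher (2 and 0 when adjusted over the list alone, 0 to 6 lower with 1 library left out and 0 with the replicate block), with a median of -0.048 (camera adjusted p = 0.0112; adjusted p = 0.673 with an estimated correlation). That call was lost after quantile normalization (0.329) and cyclic loess (0.792, with 2 higher and 4 lower), without knockdown 1 (0.153) or control 1 (0.058), with a filter of 5 FPKM (0.333) and with GC and length trends removed without and with the block (0.0699 and 0.0703). The adjusted p ranged from 0.000206 to 0.792 over 25 alternatives.

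Heat shock genes did not pass as a list (3 of 16 higher, 1 lower; 4 and 1 when adjusted over the list alone; 1 higher in each fit with a library left out and with the replicate block; camera adjusted p = 0.137), although quantile normalization and cyclic loess gave 0.0135 and 0.0119. The adjusted p ranged from 0.0119 to 0.389 over 25 alternatives. HSPH1, a cochaperone of HSP70, rose 1.34-fold (adjusted p = 0.00272).

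**Figure D3:**
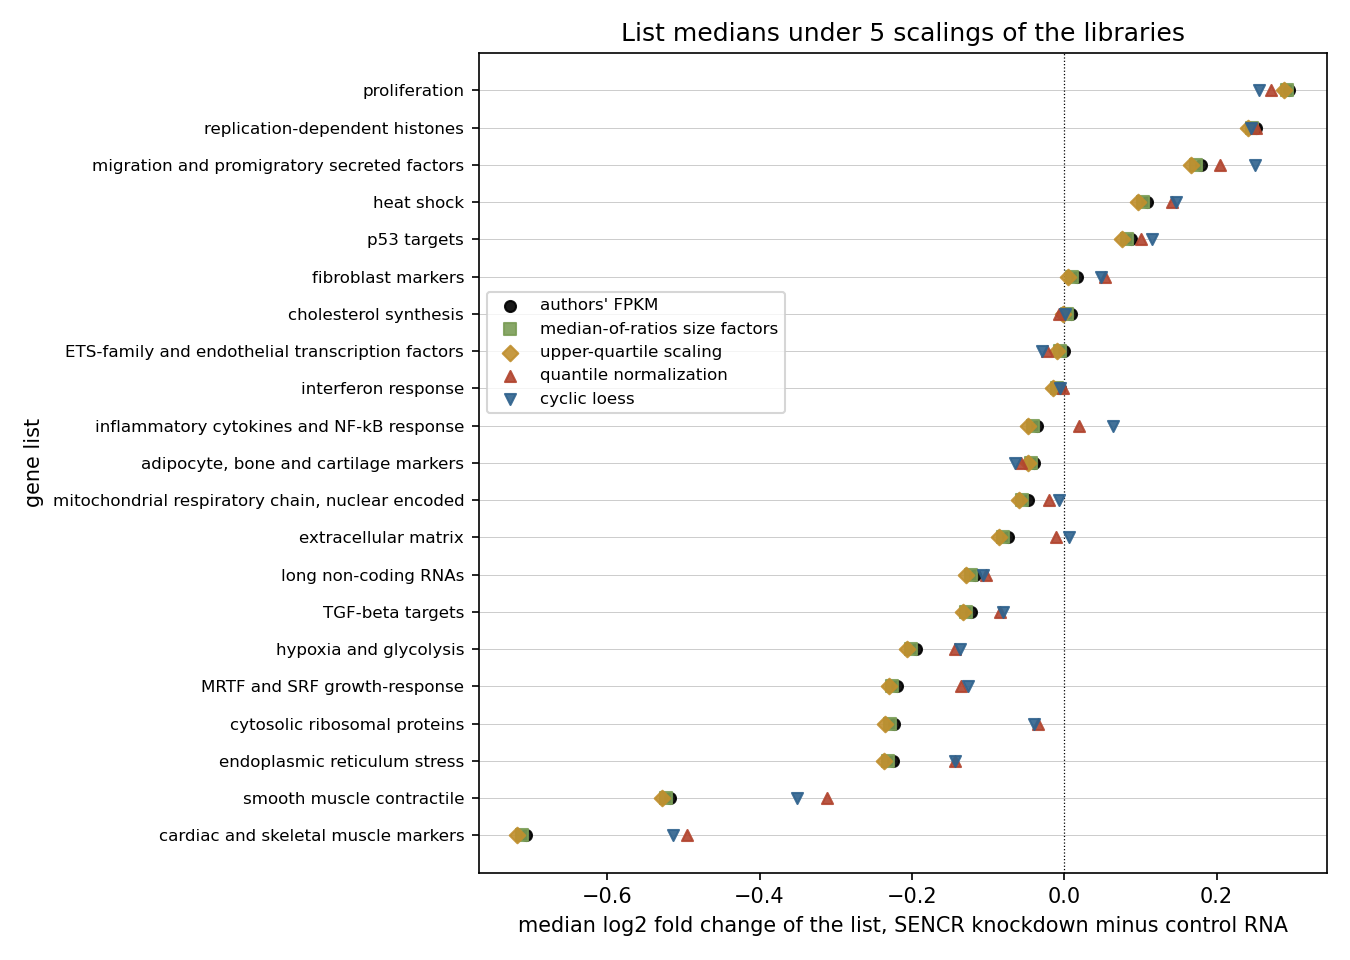
Median log2 fold change of each list, knockdown minus control, under the authors' FPKM and 4 other scalings of the libraries; each symbol is 1 scaling. The ribosomal protein median moves from -0.223 to -0.04 after cyclic loess, and the proliferation median from 0.295 to 0.256.

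Inflammatory cytokine and NF-kB genes did not move as a list (1 of 32 tested higher and 8 lower, 2 and 9 when adjusted over the list alone, camera adjusted p = 0.139), and their median of -0.036 turned to 0.02 after quantile normalization (6 higher and 5 lower) and 0.064 after cyclic loess (7 higher and 4 lower). With 1 library left out 3 to 5 were lower. Single cytokines fell: IL6 from 398 ± 21.8 to 230.2 ± 19.5 (adjusted p = 0.00292), IL1A from 36.7 ± 1.63 to 25.5 ± 1.21 (adjusted p = 0.00331) and CCL20 2.28-fold (adjusted p = 0.00693), while the receptor gene IL1R1 rose 1.30-fold (adjusted p = 0.00364). Interferon response genes had 0 of 40 tested higher and 4 lower (camera adjusted p = 0.611). The counts were 0 and 1 when adjusted over the list alone, with 1 to 3 lower when 1 library was left out and 2 with the replicate block. That list passed only without knockdown 2 (0.0182), in a range of 0.0182 to 0.926 over 25 alternatives. Both groups were given an RNA, so an interferon reaction to introduced RNA that both shared would not show in this comparison. OAS3 fell 1.37-fold (adjusted p = 0.0121).

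Cholesterol synthesis genes had 1 of 21 higher and 2 lower over all genes and over the list alone, and 0 and 0 with the replicate block (camera adjusted p = 0.91). LSS was at 13.6 and 11.6 FPKM (adjusted p = 0.0415) and INSIG1 at 22.9 and 26.3 (adjusted p = 0.0352). Both calls were lost without knockdown 2 or any 1 of the controls (LSS also without knockdown 3, INSIG1 also without knockdown 1), with adjusted p up to 0.116 and 0.101. ETS-family and endothelial transcription factors had 2 of 25 higher and 2 lower (camera adjusted p = 0.8): ETV1 (1.29 against 0.847 FPKM) and FLI1 were higher, ETS1 and TEAD1 lower. Of these, ETV1 was lost without knockdown 1 or control 2 (adjusted p up to 0.0512) and TEAD1 without any 1 knockdown or control 2 (adjusted p up to 0.0629). Listed long non-coding RNAs had 5 of 22 tested lower and 0 higher, also when adjusted over the list alone (2 or 3 lower with 1 library left out), with a median of -0.117 (camera adjusted p = 0.0123; adjusted p = 0.359 with an estimated correlation). The list's call was lost without knockdown 1 (0.0589) and with a filter of 5 FPKM (0.156), in a range of 0.0065 to 0.156 over 24 alternatives. MIR22HG fell 1.28-fold (adjusted p = 0.00364), and the small nucleolar RNA hosts GAS5 and SNHG5 were 1.28- and 1.32-fold lower (adjusted p = 0.027 and 0.0327). GAS5 was lost without any 1 library (adjusted p up to 0.0697) and SNHG5 without any but control 3 (up to 0.0937). MIR143HG, the host of the smooth muscle microRNAs 143 and 145, was below the filter, at 0.499 ± 0.0798 against 0.93 ± 0.111.

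Markers of other cell types were mostly too low to test. Of the endothelial list 4 members passed the filter: EGFL7 was at 4.81 and 5.25 FPKM (adjusted p = 0.327) and TEK at 1.58 and 1.30 (adjusted p = 0.0409, lost without any 1 library, up to 0.111). CDH5 was at 0.313 and 0.235 FPKM. Fibroblast markers went both ways, 2 of 11 higher and 3 lower over all genes and over the list alone (camera adjusted p = 0.556): MFAP5 fell 1.74-fold (adjusted p = 0.00529), SFRP4 fell 1.71-fold (adjusted p = 0.00796) and PDGFRA rose from 29.4 to 35.3 FPKM (adjusted p = 0.00629). FAP, at 67.3 and 79 FPKM, lost its call without knockdown 1 or 2 (adjusted p up to 0.0545). CD68 was the one leukocyte marker tested, at 30 ± 1.7 against 20.8 ± 2.56 FPKM (adjusted p = 0.0174, lost without knockdown 1, knockdown 3 or control 3, up to 0.0575). All 5 tested cardiac and skeletal muscle genes fell over all genes and over the list alone, with a median of -0.706 (camera adjusted p = 1.74e-05; adjusted p = 0.25 with an estimated correlation), led by NPPB and ACTC1, the cardiac actin (2.16-fold, adjusted p = 0.00238), which shares near-identical sequence with ACTA2. MYH6, at 2.61 and 3.09 FPKM, lost its call without knockdown 1, knockdown 3 or any 1 of the controls (adjusted p up to 0.0584). Of 3 epithelial keratins tested KRT5 fell from 1.33 to 0.781 FPKM (adjusted p = 0.00871), and KRT18 and KRT8 were 1.38- and 1.13-fold lower (adjusted p = 0.0199 and 0.0413), calls lost in 5 and 6 of the 6 fits with a library left out (up to 0.0689 and 0.116). Fat, bone and cartilage markers had 1 of 7 higher and 2 lower (camera adjusted p = 0.237), with TNFRSF11B the largest fall.

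In untreated cells the authors' mean FPKM reached 1 in 21458 rows, 19555 of them named and 1903 without a name, and 26580 rows were listed at 0. These are means of 3 libraries with no spread given. Cytoskeletal and matrix genes stood high: ACTB at 2143, TAGLN at 813, COL1A2 at 1694 and TGFBI at 2656 FPKM, and the chemokine genes IL8 and CXCL1 at 1003 and 891, a choice made after the values were seen. Of the study's other genes ACTA2 was at 128.3, MDK at 23, CNN1 at 8.63, MYOCD at 4.05, LMOD1 at 1.83, MYH11 at 1.69 and PTN at 0.35.

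Only 18 of the 51 listed long non-coding RNAs had a row in untreated cells. The 5 highest of these were SNHG5 at 88.2, MEG3 at 79.4, GAS5 at 53, SNHG6 at 34.7 and SNHG8 at 31.2 FPKM. In all, 318 names of long non-coding RNAs in GENCODE reached 1 FPKM. FLI1 was at 24.1 FPKM in its highest row (11:128561557-128683161), ETS1 at 27.3, and 2 rows without a name at the FLI1 interval at 7.66 and 0.553; neither carries the name SENCR. Of markers of other lineages with a row, 8 of 20 endothelial, 9 of 15 fibroblast, 2 of 20 leukocyte, 2 of 17 muscle, 2 of 11 epithelial and 6 of 17 fat, bone and cartilage genes reached 1 FPKM. The highest included EGFL7 at 40.9, SOX17 at 15.9 and CDH5 at 14.3 (endothelial), C3 at 200.9 and MFAP5 at 162.8 (fibroblast), CD68 at 18.8 and CD14 at 17.8 (leukocyte), NPPB at 77.4 and TNNT1 at 8.72 (muscle), KRT19 at 4.38 and CLDN4 at 2.35 (epithelial), and MGP at 31.6 and BMP2 at 16.8 (bone and cartilage). The 10 highest named rows were FTLL2 at 16153, C17orf99 at 13418, AC100843.2 at 12717, TJP1 at 10044.6, RP11-278L15.3 at 9974, AC027667.1 at 9878, RP11-326I19.1 at 9490.5, ZNF418 at 8458, NEK9 at 8208 and JAM3 at 8129 FPKM, each a name with more than 1 row. Of the 100 highest rows 48 had an interval under 200 bp and 37 no name, and in such short rows a few reads give a large FPKM. That leaves 7 of the 10 highest named rows unexplained, whose intervals span 2649 bp or more.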

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

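The tests with cyclic loess, with GC and length trends removed, and with small RNAs, rows with a 0 or rows sharing a locus left out were chosen only after the results were seen; the other alternatives were planned. Causes of these differences were not tested. The counts of changed, higher and lower genes (1963, 865 and 1098) stayed within 1.5 times under every pseudocount, scaling, empirical Bayes and weighting alternative. They were 557, 195 and 362 at an adjusted p of 0.01. With a filter of 5 FPKM, 1256 genes changed and 388 rose, among 5000 tested. Leaving out 1 library, so with fewer samples, gave 961 to 1127 changed, 376 to 440 higher and 527 to 714 lower, and 9 to 13 changed markers of other cell types in place of 18. FLI1 was then at 0.143 to 0.188; without a filter it was at 0.171 (adjusted p = 0.0539).

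The labels give both groups the numbers 1 to 3 but no shared day or culture, and same-numbered libraries hardly deviated together (correlations of deviations 0.033, 0.016 and 0.017, against a limit of 0.1), although 4 of 6 libraries were closest to their own number. With the replicate block 688 genes changed (285 higher, 403 lower), 11 markers were called, FLI1 was at 0.171 (adjusted p = 0.0596) and the migration list at 0.0512. With the replicate block and GC and length trends removed, 816 genes changed (358 higher, 458 lower), FLI1 was at 0.18 (adjusted p = 0.0561) and the respiratory chain list at 0.0703. The block changed no other list's call, but 0 ribosomal protein genes were then lower in place of 38.

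Of the 14 lists past camera, 8 passed with a filter of 5 FPKM, where proliferation and cardiac and skeletal muscle genes were not tested, with 2 members left in each, and p53 targets (0.423), TGF-beta targets (0.449), the respiratory chain (0.333) and long non-coding RNAs (0.156) lost their call, the respiratory chain with all its 54 members still tested. Without rows sharing a locus, 9 lists passed, long non-coding RNAs and cardiac and skeletal muscle genes were not tested, with 3 members left in each, and migration (0.0684), p53 targets (0.0508) and TGF-beta targets (0.0684) lost theirs. Quantile normalization ended the calls of extracellular matrix (0.329), TGF-beta targets (0.109) and the respiratory chain (0.329), as did cyclic loess (0.472, 0.209 and 0.792), and both called heat shock (0.0135 and 0.0119). TGF-beta targets were also lost with median-of-ratios factors (0.0564) and upper-quartile scaling (0.0509), and the respiratory chain with GC and length trends removed (0.0699). With an estimated correlation 0 lists passed: the adjusted p was 0.25 for contractile, proliferation, endoplasmic reticulum stress and cardiac and skeletal muscle genes, 0.328 for MRTF and SRF response, p53 targets and histones, 0.359 for migration, hypoxia and glycolysis, TGF-beta targets, ribosomal proteins and long non-coding RNAs, 0.404 for extracellular matrix and 0.673 for the respiratory chain. Fry lost the respiratory chain (0.36) and called fat, bone and cartilage markers (0.00995). With 1 library left out, the adjusted p ranged from 0.0133 to 0.112 for migration, 0.000206 to 0.153 for the respiratory chain, 0.0065 to 0.0589 for long non-coding RNAs, 0.0286 to 0.076 for TGF-beta targets and 0.0182 to 0.833 for interferon response.

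The genes the study examined and those with the largest changes kept their direction and side of the threshold in 623 fits, turned in 3 (SMTN) and lost their call in 14 (HIST1H2AD, MYOCD and MIR4680). Of all 118 tested genes that the naming rule covers, the leading members of each list included, 110 were called; 33 of these lost their call in at least 1 fit with a library left out and 31 with the replicate block. SMTN, not called, lay between -0.007 (without knockdown 3) and 0.071 with 1 library left out and turned to -0.006 with GC and length trends removed and -0.006 with the block as well. Untreated cells had 11480 rows at 5 FPKM or more in place of 21458 at 1; a minimum in every untreated library and leaving out untreated libraries were not run, since the table holds their mean only. Depth limits low genes most, and the read numbers of small RNA rows are lower limits.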

Other observations

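Chosen only after the result was seen were the tests on fibroblast, endothelial, leukocyte, epithelial and muscle markers and on actin and transgelin paralogs in untreated cells, the bootstrap interval of the contractile median, the alternatives with cyclic loess and with GC and length trends removed, and the genes of thrombin signalling, of steroid and aldehyde metabolism and of secreted, signalling and other factors described here. Some genes of thrombin and plasmin signalling were higher in knockdown along with THBD. The thrombin receptor F2R (PAR1) went from 9.91 ± 0.741 to 14.8 ± 0.728 FPKM (limma adjusted p = 0.00477) and its neighbour F2RL1 (PAR2) from 2.16 ± 0.0777 to 4.16 ± 0.272 (1.93-fold, adjusted p = 0.00166). The urokinase gene PLAU rose from 1.58 to 2.86 FPKM (adjusted p = 0.00263), the collagen receptor subunit ITGA2 from 27 ± 0.182 to 43.2 ± 0.956 (adjusted p = 0.000836) and the bradykinin receptor BDKRB1 1.56-fold (adjusted p = 0.00155). Some genes that handle steroids and aldehydes were also higher: AKR1C1, AKR1C2 and AKR1C3 rose 1.73-, 1.72- and 1.72-fold beside AKR1C4 (adjusted p = 0.00292, 0.00295 and 0.00321), although reads cannot be divided with certainty among such close copies, and HSD11B1, which regenerates cortisol, 1.73-fold (adjusted p = 0.0028). The more distant AKR1B1 and AKR1B10 were at 136.1 and 19.9 FPKM in knockdown and 127.9 and 18.1 in control (adjusted p = 0.228 and 0.092). These groups were not tested for enrichment.

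Some secreted and signalling genes were lower, although others, such as MDK, PTN and PLAU, were higher. The metalloproteinase inhibitor TIMP3 went from 100.4 ± 6.2 to 46.7 ± 3.3 FPKM (2.15-fold, adjusted p = 0.00155), IGFBP3, which binds insulin-like growth factors, from 401 ± 32.4 to 192.4 ± 11.6 (2.08-fold, adjusted p = 0.00173), and EDN1, the vasoconstrictor endothelin-1, from 3.29 ± 0.275 to 1.56 ± 0.179 (adjusted p = 0.00295). DDAH1, which breaks down an inhibitor of nitric oxide synthase, fell 1.84-fold (adjusted p = 0.000416), the calcineurin regulator RCAN1 1.98-fold (adjusted p = 0.00314), ENC1 2.12-fold (adjusted p = 0.000499) and KRT7 2.14-fold (adjusted p = 0.0011). INHBE, a target of ATF4 like CHAC1 and ASNS, fell from 2.26 to 0.805 FPKM (adjusted p = 0.00155). PLAU, TIMP3 and RCAN1 share their interval with another row, so their reads are uncertain.

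The contractile list was lower in knockdown, with 28 of 35 tested members called and a median log2 fold change of -0.518. A trend of fold change with expression level is argued against as the whole cause, since cyclic loess left a median of -0.351 (bootstrap 95% interval -0.532 to -0.256) and 27 of 35 members lower, with part of the fall taken away. The bound of -0.35 set beforehand was met only barely, and the median after the planned quantile normalization, given above, did not reach it. The argument therefore rests on the cyclic loess interval staying below -0.2, a criterion set after the value was seen. Members of the list vary together between libraries (estimated correlation 0.388), so the interval may be too narrow. Fibroblast markers went both ways, with 3 past the threshold downwards (MFAP5, SFRP4 and FAP) beside 2 upwards. The criterion for them was set after these counts were seen, so a larger share of fibroblasts cannot be excluded. All 3 epithelial and all 5 striated muscle markers tested were lower, not higher as a larger share of those cells would make them. With the replicate block, 1 epithelial and 4 muscle markers were still called. Of the muscle markers, ACTC1 and ACTA1 may share reads with ACTA2. Endothelial cells and leukocytes are argued against by level alone, and only by the levels in the knockdown libraries. Of 23 endothelial markers 19 were under 1 FPKM in knockdown. VWF, PECAM1 and CDH5 were at 0.0175, 0.354 and 0.313 FPKM, although above the 0.0113, 0.28 and 0.235 in control. TEK, EGFL7, SOX17 and ECSCR reached 1 FPKM in knockdown, of which TEK was called higher (limma adjusted p = 0.0409) and 3 were not called. Of 20 leukocyte markers 15 were under 0.1 FPKM in knockdown, although CD68 rose. In untreated cells, normalized separately, 8 of 20 endothelial and 2 of 20 leukocyte markers with a row reached 1 FPKM, with EGFL7 highest at 40.9. Removal of GC and length trends left a median of -0.523. Reads shared with paralogs cannot be told apart from a change of these genes: the median without ACTA2, ACTG2 and TAGLN was -0.461, but leaving out any 3 of the 35 members gives -0.461 at most, and other members with paralogs, such as TPM1 and CNN1, stayed in. A response to the lowered SENCR, effects of the knockdown RNA on other targets and a share of fibroblasts or of fat, bone, cartilage or unlisted cell types stay open.

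Ribosomal protein genes had a median of -0.223, with 38 of 77 called lower. Removal of GC and length trends left -0.196. Length and GC content were those of the longest GENCODE transcript of each name, which need not be the one measured, so these causes cannot be excluded. A larger share of summed FPKM in a few listed genes is argued against. The 10 highest rows held 13.6 ± 0.48% in knockdown and 13.1 ± 0.29% in control, 0.49 percentage points apart where at least 5 were needed. FPKM is scaled by length and mitochondrial rows are absent, so shares of reads, and shares of transcripts without a row, were not measured. A trend with expression level cannot be told apart from a change of these genes: cyclic loess left -0.04, and the list's median lay at percentile 3.44 of 10000 lists matched on expression, whose own median was -0.176. A response to the knockdown also stays open.

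The sarcomeric actins and other paralogs fell together with ACTA2 and TAGLN: ACTC1, ACTA1, ACTBL2 and TAGLN3 were 2.16-, 1.64-, 2.53- and 2.01-fold lower. If reads of the abundant genes were given to them, they could be high here and near 0 in the separately built untreated table, which held for 2 of the 4. ACTC1 was at 18.3 and ACTA1 at 165.2 FPKM or more in the 6 libraries but at 0.0099 and 0.0576 in untreated cells, while ACTBL2 (7.03 or more against 5.93) and TAGLN3 (33.1 or more against 4.22) were not near 0. Shared reads and a change of the paralogs themselves cannot be told apart, because the sources give no rule for dividing reads.

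The 6 libraries can be split into groups of 3 in 10 ways, too few for a share under 0.05: the real split, 1 of the 10, called 1963 genes and the highest other split 5.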
